A study of Mus musculus with 12 samples.

How the data were processed

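The study hybridised biotin-labelled total RNA from 12 BMEL cultures to Affymetrix whole-genome mouse arrays, with 2 biological replicates for each of the 6 combinations of line (9A1 and 14B3) and culture (basal, aggregate for 1 day, aggregate for 5 days). The deposited values are log2 probe set levels, summarised by the authors with RMA in R 2.3.1 per the submitters' processing notes. RMA subtracts background, normalises all arrays to one distribution and summarises probes, so differences in total RNA between cultures are not seen, and levels near the top of the scale are compressed. The file held 45101 probe sets, and 0 of its columns of values were left unmapped. It gives no detection calls, and scans and background levels are not used here.

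Probe sets were joined to genes with a platform annotation. Of the probe sets 34945 had 1 gene, 932 had several, 9160 had no gene listed and 64 were controls, and the last 3 kinds were left out. For 34741 probe sets the Entrez identifier was in the RefSeq table of assembly GRCm38, which gave gene positions. These made 18193 genes, of which 9010 had more than 1 probe set; the probe set with the highest mean over the 12 arrays stood for the gene. Genes with a log2 level of at least 5 on at least 2 arrays were tested, 15781 in all.

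The analysis used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. One linear model with a mean for each of the 6 groups was fitted by limma to all 12 arrays, with empirical Bayes moderation and a trend in the variance. Contrasts compared 1 day with basal, 5 days with basal and 5 days with 1 day, each averaged over the lines, as well as 9A1 with 14B3 averaged over the cultures, the lines in basal culture, and the difference between the lines in each response (interaction). Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons with basal culture share the basal arrays, so overlap between them was not assessed. Replicate numbers were not used as pairs.

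In total 24 gene lists were tested by camera from limma with its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and by fry. The lists cover hepatocyte, biliary, fetal liver and progenitor surface markers, liver transcription factors, junctions, integrins, matrix, contractile genes, YAP, Wnt, Notch and TGF-beta and BMP targets, replication, mitosis, cell cycle inhibitors, hypoxia, cholesterol synthesis, stress, interferon, inflammation and 3 other cell types. Of their 576 genes 543 were on the array table, 4 through an older symbol. The lists, tests, filters and naming rule were fixed before the data were examined. The rule names, among called genes with the same sign in both lines, the 5 largest rises and falls per comparison, in each called list the 3 called members that changed most in its direction and 1 against it, the 4 largest rises and falls among surface families at 5 days, and every gene of a 10 gene marker panel. For lines and interactions it names the 5 largest each way. Surface families were compared with all genes by Fisher's exact test.

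The model was tested on simulated data built on the 15781 genes, in which 200 genes changed by a known amount. Of genes changed 4-fold it recovered 95% at 1 day, 91% at 5 days and 97% between lines, and of genes changed 2-fold 58%, 50% and 72%. For the interactions it recovered 50% and 45% of 4-fold differences at 1 and 5 days. The real replicate pairs were unequal. The SD of the pair difference was 0.896, 0.779 and 0.405 for 9A1 in basal culture, at 1 day and at 5 days. For 14B3 it was 0.253, 0.300 and 0.196. The simulated data were not shown to share this inequality or correlation between genes, so these rates may not hold for the real arrays.

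Alternatives tried were no filter and a floor of 6, the mean of probe sets, every probe set on its own, median centring, quantile normalisation, array weights, robust moderation, no variance trend, an additive model, only the cultures compared, each line alone, a replicate block, a 2-fold minimum, adjusted p under 0.01, and leaving out each array. Leaving out basal 9A1 replicate 1 together with day 1 9A1 replicate 2 was added after the data were seen.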

Results

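Gene expression was measured with Affymetrix whole-genome mouse arrays in 2 bipotential mouse embryonic liver (BMEL) cell lines, 9A1 and 14B3. BMEL lines are immortal epithelial lines from fetal liver that can be directed towards hepatocytes or bile duct cells in culture, and per the labels these came from liver at day 14 post coitum. Each line was grown in basal culture, where the cells stay adherent and proliferate, and as floating aggregates for 1 day and for 5 days. The 6 combinations of line and culture had 2 biological replicates each, 12 arrays in all. The array medians lay between 6.09 and 6.24 on the log2 scale. The number of arrays limits the precision of every value, and the deposited values carry no detection calls. Unless stated otherwise, differences are in log2 units with the limma standard error, over 4 arrays per culture, and p-values are adjusted for the 15781 genes tested.

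Except for basal 9A1 replicate 1, the arrays of the 3 cultures separated along the first principal component, which held 60.03% of the variance. Basal 9A1 replicate 1 scored -11.7 on it, while the other basal arrays scored between 69.5 and 78.8, the 1 day arrays between 3.29 and 25.8 and the 5 day arrays between -83.8 and -61.4. Hepatocyte genes were high on this array. Albumin (Alb) stood at 13.1 against 5.57 to 6.86 on the other basal arrays, and transthyretin (Ttr) at 13.1. Its correlation with its replicate across probe sets was 0.952, and its closest array was 5 day 14B3 replicate 1, with 0.976. Day 1 9A1 replicate 2 had the narrowest spread of values, with an SD of 2.13 against 2.25 to 2.33 on the other arrays, and a correlation of 0.949 with its replicate. Both arrays were kept in every comparison. Probe sets are not independent replicates, so these correlations describe arrays and carry no test.

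**Figure D1:**
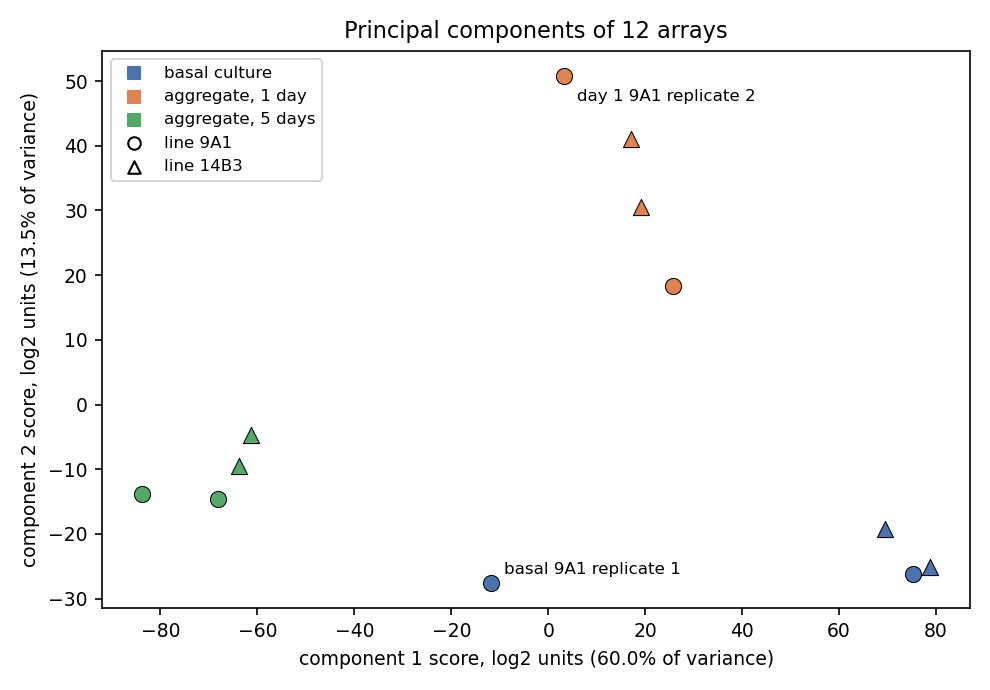
Scores of the 12 arrays on the first 2 principal components of the log2 levels of the genes tested, in log2 units, with 60.03% and 13.5% of the variance. Colour marks the culture and shape the line, and basal 9A1 replicate 1 lies at -11.7 on component 1, between the other basal arrays and the 5 day arrays.

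The comparison of 1 day of aggregate culture with basal culture asks which genes respond early when the cells leave the dish. Cdc6, which loads the replicative helicase at origins, fell by 3.96 ± 0.19, a 15.6-fold difference (adjusted p = 7.93e-05). Cyclin E2 (Ccne2) fell by 3.75 ± 0.30. Its 1 day mean of 4.45 lies under the floor of 5, so background limits the size of this fall. The cohesion genes Dscc1 and Esco2 changed by -3.42 ± 0.24 and -3.38 ± 0.24. The largest rises were in Cyp2c55, a cytochrome P450, at 5.32 ± 0.84 (39.8-fold, adjusted p = 0.00426), Ttr, a plasma carrier protein made by liver, at 4.67 ± 1.20 (25.4-fold, adjusted p = 0.0325), and the folate receptor gene Folr1 at 3.56 ± 0.29 (11.8-fold, adjusted p = 0.000387). Maob, a monoamine oxidase, and the retinal dehydrogenase gene Aldh1a1 rose 10.3-fold and 8.01-fold, while cardiac troponin T (Tnnt2) fell by 3.66 ± 0.92. The 9A1 basal arrays moved the size of these changes. With replicate 1 and replicate 2 left out in turn, Cyp2c55 rose by 6.43 and 4.20, Ttr by 6.40 and 2.93, Maob by 4.26 and 2.46 and Aldh1a1 by 4.11 and 1.90, and Tnnt2 changed by -4.73 and -2.60. Aldh1a1 changed by 0.71 in 9A1 and 5.29 in 14B3, a difference that did not pass the interaction test (adjusted p = 0.940).

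Among the 31 tested genes of DNA replication, 29 fell and 0 rose at 1 day, with a median change of -2.10 (camera adjusted p = 6e-28). The adjusted p = 0.156 with an estimated correlation. Adjusted over the list alone the count was also 29. Gins1, part of the helicase, fell by 3.08 ± 0.24. Of 29 mitosis genes, 28 fell, and 29 did so adjusted over the list alone (camera adjusted p = 1.92e-25, adjusted p = 0.347 with an estimated correlation). The kinase genes Aurkb, Bub1 and Ttk fell by 2.74 ± 0.27, 2.62 ± 0.29 and 2.55 ± 0.28. On the mean of the mitosis list basal 9A1 replicate 1 lay at 9.79 and the other basal arrays at 10.8 to 10.9.

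Of 22 tested genes of stress response and amino acid starvation, 12 fell and 0 rose at 1 day (2 rose without basal 9A1 replicate 1), and 13 fell adjusted over the list alone (camera adjusted p = 4.56e-07, adjusted p = 0.156 with an estimated correlation, which was 0.036 without basal 14B3 replicate 1). Psat1, of serine synthesis, fell by 3.09 ± 0.39, the pseudokinase gene Trib3 by 2.46 ± 0.25, and Chac1, which degrades glutathione, fell by 2.27 ± 0.22. In basal culture Chac1 was lower in 9A1 by 3.24, while the 1 day arrays all lay between 6.01 and 6.71. Its mean fall therefore describes neither line, although the interaction test called 0 genes at 1 day. Of 16 targets of YAP, a coactivator that responds to cell spreading, 5 fell and 7 did so adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.600 with an estimated correlation). Ccn1, Ccn2 and tissue factor (F3) fell by 2.21 ± 0.32, 2.15 ± 0.61 and 1.77 ± 0.38. Of 15 TGF-beta and BMP targets, 3 fell, namely Id3 by 1.99 ± 0.33, Smad7 by 0.68 ± 0.15 and Id1 by 0.49 ± 0.10, and 6 fell adjusted over the list alone (camera adjusted p = 0.0093, adjusted p = 0.598 with an estimated correlation). In cholesterol synthesis 1 of 19 genes fell, Hsd17b7, by 0.96 ± 0.22, and adjusted over the list alone the count was the same (camera adjusted p = 0.00987, adjusted p = 0.817 with an estimated correlation). On this list day 1 9A1 replicate 1 lay at 9.41 and the other 1 day arrays at 10.8 or more. With 1 array left out, the number that fell ran from 8 to 13 for the amino acid list, from 2 (without any 1 of the 4 basal and day 1 arrays of 14B3) to 9 (without basal 9A1 replicate 1) for YAP targets, from 1 (without any 1 of the same arrays) to 6 (without basal 9A1 replicate 1) for TGF-beta and BMP targets. It ran from 0 (without basal 14B3 replicate 1 or a day 1 14B3 array) to 16 (without day 1 9A1 replicate 2) for cholesterol synthesis. Ccn2 fell by 2.76 without day 1 9A1 replicate 1 and fell by 1.54 without replicate 2.

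Liver transcription factors were the 1 list called upward at 1 day, with 3 of 21 members rising, 3 also when adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.600 with an estimated correlation). The xenobiotic receptor gene Nr1i2 rose by 1.73 ± 0.45, Hhex, needed for liver budding, by 1.55 ± 0.32, and Hnf4a, a central hepatocyte regulator, by 0.82 ± 0.17 (adjusted p = 0.0149). The number that rose was 7 without basal 9A1 replicate 1, 6 without day 1 9A1 replicate 1, 1 without day 1 14B3 replicate 1 and 0 without basal 14B3 replicate 1 or day 1 14B3 replicate 2, and Nr1i2 rose by 2.32 and 1.14 without basal 9A1 replicate 1 and replicate 2. Of 38 genes of hepatocyte function 4 rose and 0 fell, 3 rose adjusted over the list alone, and the list was not called (camera adjusted p = 0.295, adjusted p = 0.817 with an estimated correlation). When basal 9A1 replicate 1 was left out it was called upward with 11 risen (camera adjusted p = 0.00132), as were biliary epithelium (0.0344), epithelial junctions (0.0143) and interferon response (0.0171), while contractile genes (0.0129) and inflammation (0.0350) were called downward, each with an adjusted p from 0.312 to 0.494 with an estimated correlation. No hepatocyte gene rose without any 1 of the 4 basal and day 1 arrays of 14B3, and 4 fell without basal 9A1 replicate 2. Hypoxia and glycolysis was called downward without basal 9A1 replicate 2 (0.00494, adjusted p = 0.877 with an estimated correlation). Of the marker panel only Hnf4a passed at 1 day with all arrays. The change in Alb was 1.25 ± 1.23, in Epcam 1.81 ± 0.97, in the fetal liver gene Afp -0.39 ± 0.75, in Cd44 -0.39 ± 0.49 and in Cd24a -0.06 ± 0.38. In 9A1 Alb lay at 13.1 and 6.86 in basal culture and at 9.99 and 7.39 at 1 day. In 14B3 it lay at 6.20 and 5.57 and at 9.79 and 9.58, so the mean change in Alb joins unlike changes of the lines. Alb rose by 2.81 (adjusted p = 0.0266) and Epcam by 3.25 (adjusted p = 3.3e-05) without basal 9A1 replicate 1, and without replicate 2 Prom1 fell by 1.51 (adjusted p = 0.00314), with 3 of its 4 arrays at 1 day under the floor of 5, so background limits this fall. Lists of blood, endothelial and stellate cell markers were not called (adjusted p from 0.425 to 0.634).

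In all, limma called 2217 genes at 1 day, 829 higher and 1388 lower, and 965 of them differed at least 2-fold. Of the 2217, 2211 had the same sign in both lines, which calling genes on the mean of both lines favours. With quantile normalisation the counts were 1315 higher and 1391 lower. Without basal 9A1 replicate 1 limma called 3574 genes, without day 1 9A1 replicate 1 4793, without basal 14B3 replicate 1 and replicate 2 853 and 1170, without day 1 14B3 replicate 1 and replicate 2 1107 and 903, and without day 5 14B3 replicate 1 and replicate 2 1476 and 1475. Of the 27 called genes named by the rule, 15 passed with any 1 array left out, whereas Ttr, Maob, Aldh1a1, Tnnt2, Nr1i2, Hhex, Hnf4a, Ccn2, F3, Hsd17b7, Smad7 and Id1 missed it without at least 1 array, all 12 without basal 14B3 replicate 1 or either day 1 14B3 array and 0 without basal 9A1 replicate 1, up to an adjusted p of 0.183 for Ccn2 without basal 14B3 replicate 1. Of the lists, liver transcription factors (adjusted p = 0.184) and YAP targets (0.131) were lost without basal 9A1 replicate 2, the former also without either day 1 9A1 array, cholesterol synthesis (0.732) without day 1 9A1 replicate 1 and TGF-beta and BMP targets (0.0573) without day 1 9A1 replicate 2.

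The comparison of 5 days of aggregate culture with basal culture asks which genes, and which surface markers, separate later aggregates from adherent, proliferating cells. The labels give the culture and no separate measure of differentiation. Lypd8 rose by 7.17 ± 1.50, the carboxylesterase gene Ces2a 128-fold, and the cytochromes Cyp2c29 and Cyp2c55 by 6.75 ± 0.46 (108-fold, adjusted p = 3.32e-05) and 6.72 ± 0.84. An unnamed transcript, 2010106E10Rik, rose by 7.05 ± 0.83. In basal culture it lay at 8.84 on 9A1 replicate 1 and at 3.92 to 3.97 on the other 3 arrays, and Lypd8 at 13.8 and at 4.83 to 5.12, near or under the floor of 5, so background limits the size of these rises. The thrombin receptor gene F2r fell by 5.25 ± 0.54 and caveolin 1 (Cav1), which coats membrane pits, by 5.22 ± 0.36 (37.3-fold, adjusted p = 3.32e-05). Aldh3a1, Tnnt2 and Bex1 fell by 5.16 ± 0.55, 4.97 ± 0.92 and 4.87 ± 0.64. The 5 day mean of Aldh3a1, 4.71, lies under the floor of 5, so background limits the size of its fall. The basal 9A1 arrays moved these values. Leaving out replicate 1 and replicate 2 in turn gave 9.34 and 5.00 for Lypd8, 8.43 and 5.57 for Ces2a, 8.28 and 5.82 for 2010106E10Rik, 7.84 and 5.61 for Cyp2c55, 7.38 and 6.12 for Cyp2c29, -6.03 and -3.90 for Tnnt2 and -5.88 and -4.45 for Aldh3a1. Probe sets of the Cyp2c and Ces2 families can hybridise with paralogs, so a change may belong to a relative of the named gene.

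Of 38 tested genes of hepatocyte function, 22 rose and 0 fell, and 23 rose adjusted over the list alone (camera adjusted p = 1.84e-08, adjusted p = 0.454 with an estimated correlation). Ttr rose by 5.55 ± 1.20, and the apolipoprotein genes Apoa4 and Apoc3 by 5.54 ± 1.31 and 5.46 ± 1.33. Alb, on chromosome 5 from 90460870 to 90476602 in the mouse assembly GRCm38, rose by 4.99 ± 1.23 (31.8-fold, adjusted p = 0.0114). A list of absorptive gut genes, written after the largest changes were seen, rose as well, in 23 of 31 cases and with a median change of 3.06 against 1.68 for the hepatocyte list (camera adjusted p = 7.64e-10, adjusted p = 0.754 with an estimated correlation). Apoa4 and Apoc3 are also made by gut epithelium. Leaving out basal 9A1 replicate 1 and replicate 2 in turn gave 6.56 and 3.42 for Alb, 7.28 and 3.81 for Ttr, 7.50 and 3.58 for Apoa4, 7.42 and 3.50 for Apoc3, 3.83 and 2.44 for Ppara and 3.56 and 2.38 for Nr1i2, and 1 hepatocyte gene fell without replicate 2. The mean of the hepatocyte list was 8.22 on basal 9A1 replicate 1 and 6.12 to 6.23 on the other basal arrays. Of 21 liver transcription factors, 10 rose and 3 fell (camera adjusted p = 0.0064, adjusted p = 0.525 with an estimated correlation). The nuclear receptor genes Ppara, Nr1i2 and Nr1h4 rose by 3.13 ± 0.52, 2.97 ± 0.45 and 2.16 ± 0.38, and Hnf4a by 0.94 ± 0.17. Foxa1, a factor that opens liver chromatin, fell by 2.10 ± 0.26.

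**Figure D2:**
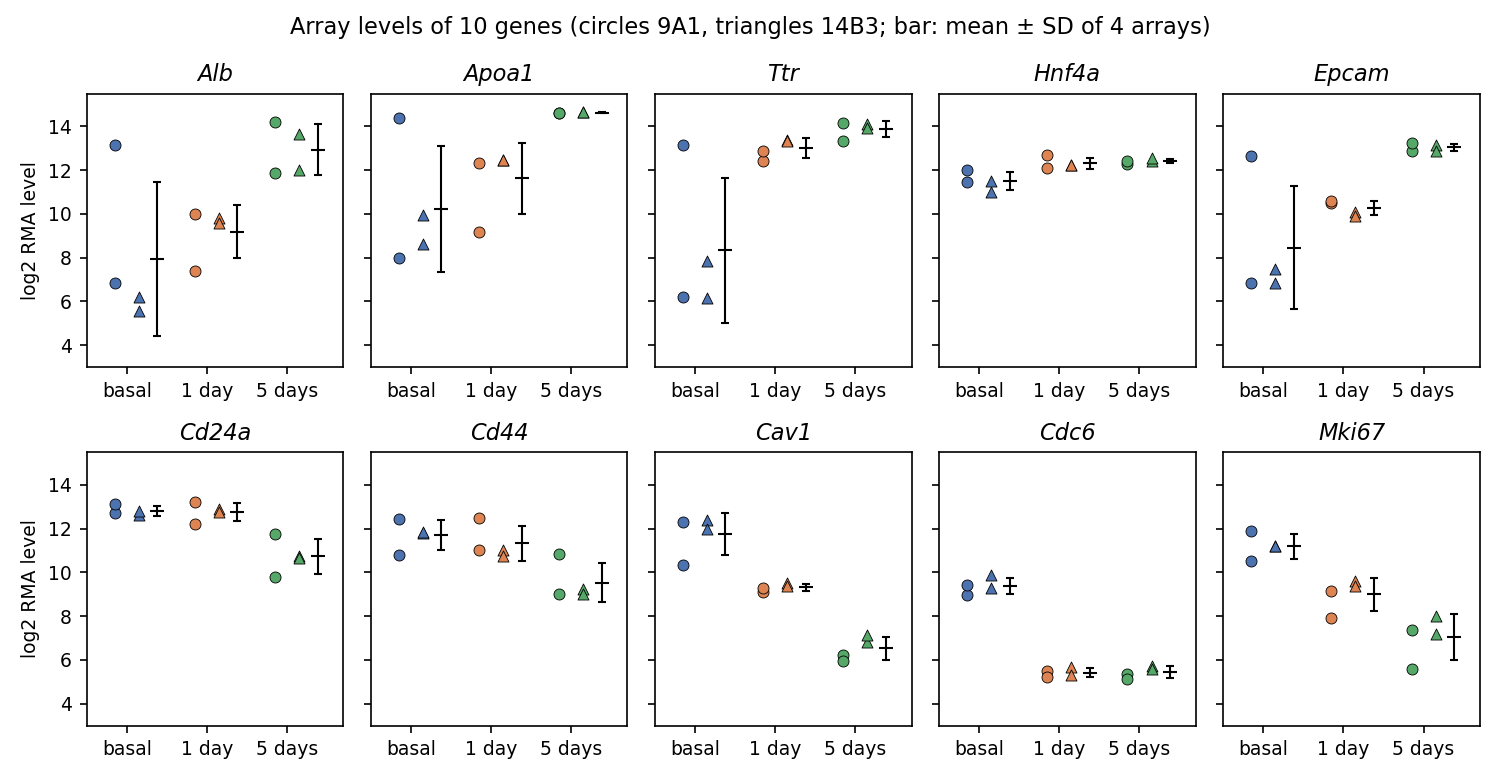
Log2 levels of 10 genes on each array in basal culture and after 1 and 5 days of aggregate culture, with circles for 9A1, triangles for 14B3 and a bar for the mean and SD of the 4 arrays of a culture. Basal 9A1 replicate 1 has Alb at 13.1 while the other basal arrays lie between 5.57 and 6.86.

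All 29 mitosis genes fell at 5 days, with a median change of -3.83 (camera adjusted p = 9.03e-23, adjusted p = 0.411 with an estimated correlation), among them Bub1 by 4.85 ± 0.29, Ube2c by 4.67 ± 0.44 and cyclin A2 (Ccna2) by 4.54 ± 0.40. Of 31 DNA replication genes 29 fell (camera adjusted p = 1.54e-19, adjusted p = 0.333 with an estimated correlation), with Rrm2, a subunit of the enzyme that makes deoxynucleotides, lower by 26.5-fold and Mcm5, a helicase subunit, lower by 19.5-fold. Cdc6, on chromosome 11 from 98907709 to 98923942, fell by 3.94 ± 0.19.

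Of 27 mesenchymal and contractile genes 15 fell and 0 rose at 5 days (camera adjusted p = 0.000221, adjusted p = 0.454 with an estimated correlation), including the actin binding genes Flna (-2.97 ± 0.49) and Cnn2 (-2.78 ± 0.36) and the lamin gene Lmna (-1.79 ± 0.26). Of 26 extracellular matrix genes 10 fell, and 12 did so adjusted over the list alone (camera adjusted p = 0.00749, adjusted p = 0.333 with an estimated correlation). Fbln2, Lamb1 and Lamb3, which encode basement membrane proteins, changed by -4.43 ± 0.64, -3.76 ± 0.45 and -2.32 ± 0.42. Of 16 YAP targets 10 fell (camera adjusted p = 0.0016, adjusted p = 0.545 with an estimated correlation), with Ankrd1, Ptpn14 and Tead1 down by 8.89-fold, 4.75-fold and 4.42-fold. Adjusted over the list alone, the counts for liver transcription factors, mitosis, DNA replication, contractile genes and YAP targets were the same as over all genes. Fbln2 changed by -5.36 and -3.50 and Ankrd1 by -3.91 and -2.40 without basal 9A1 replicate 1 and replicate 2.

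Epithelial junction genes rose in 11 of 30 cases and fell in 3, and adjusted over the list alone 15 rose and 3 fell (camera adjusted p = 0.0129, adjusted p = 0.545 with an estimated correlation). Gjb1, the main gap junction gene of hepatocytes, rose by 3.42 ± 0.74, and the tight junction genes Ocln and Marveld3 by 2.22 ± 0.63 and 1.98 ± 0.55. Basal Marveld3 lay under the floor of 5 on 2 of 4 arrays (4.71 and 4.86), so background limits the size of its rise. The gap junction gene Gja1 fell by 3.22 ± 0.40. Of the 30, 18 rose without basal 9A1 replicate 1, while 4 rose without basal 14B3 replicate 1, day 5 9A1 replicate 1 or day 5 14B3 replicate 2, and 5 without day 5 14B3 replicate 1. Of 24 interferon response genes 12 rose and 0 fell, while adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 0.000221, adjusted p = 0.454 with an estimated correlation). Parp14, the RNA sensor gene Ifih1 and Ifit3 rose by 2.54 ± 0.25, 2.10 ± 0.34 and 1.59 ± 0.15. Of 25 genes of hypoxia and glycolysis 6 rose, and 5 did so adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.545 with an estimated correlation), with Ankrd37 at 2.84 ± 0.56, Pfkp, a phosphofructokinase, at 1.97 ± 0.41 and Ndrg1 at 1.94 ± 0.50. Of these 25 genes 18 rose without basal 9A1 replicate 1 and 3 without basal 14B3 replicate 1, and 1 fell without day 5 9A1 replicate 1, while 2 interferon genes fell without basal 9A1 replicate 1. Leaving out basal 9A1 replicate 1 and replicate 2 in turn gave 4.47 and 2.37 for Gjb1, 2.99 and 1.45 for Ocln, 2.74 and 1.23 for Marveld3, 3.66 and 2.02 for Ankrd37 and 2.64 and 1.24 for Ndrg1. The lists of blood, endothelial and stellate cell markers each had an adjusted p of 0.845.

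**Figure D3:**
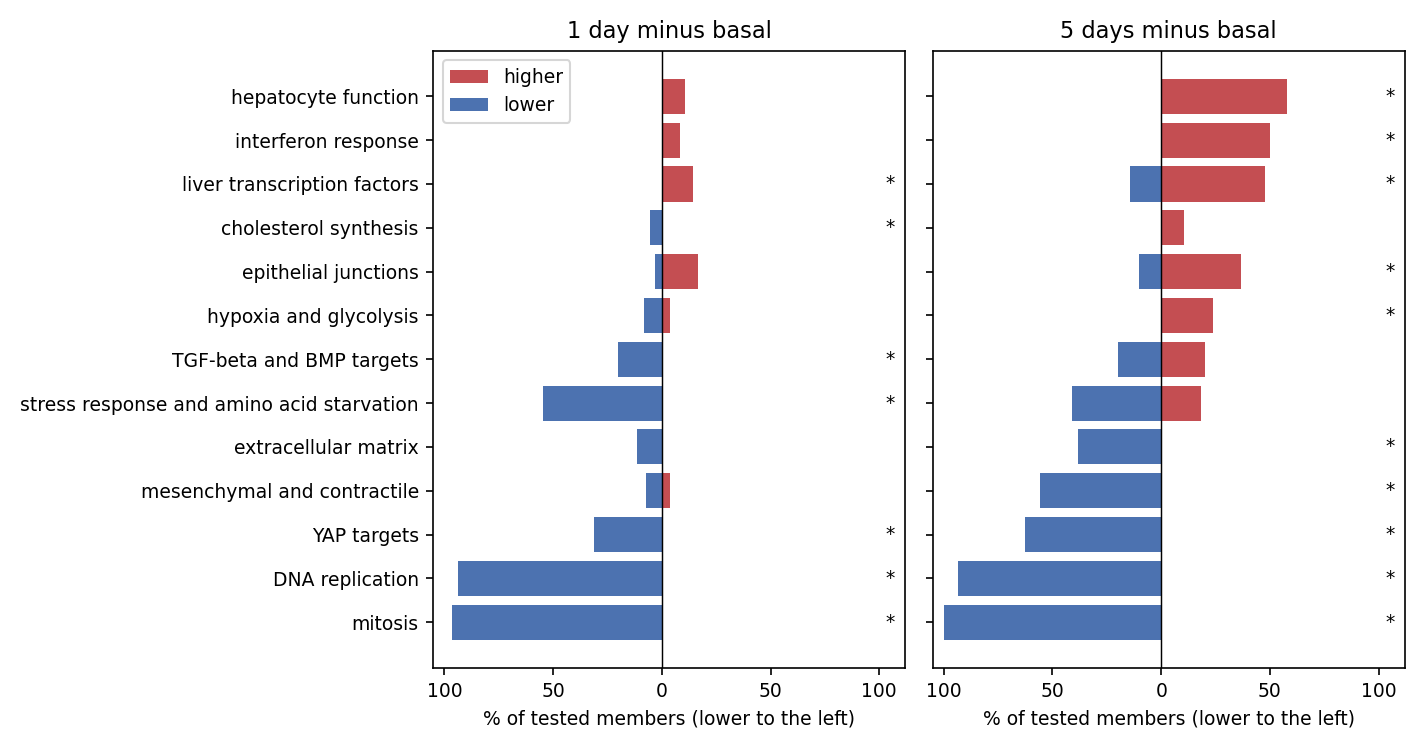
Percent of the tested members of each gene list that passed the limma test as higher (right of 0) or lower (left of 0) at 1 day and at 5 days of aggregate culture, for the lists called in either comparison, with a star where camera called the list. At 5 days all 29 mitosis genes were lower and 22 of 38 hepatocyte genes higher.

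Surface molecules were the stated aim of the series. Of 218 tested genes in surface families (CD antigens, integrins, claudins, ephrins and others) 27 rose and 35 fell at 5 days. The share that rose was 12.4% against 16.9% of all genes (Fisher's exact test, two-sided, p = 0.0831), and the share that fell 16.1% against 18.5% (p = 0.380, the same exact test). At 1 day 10 rose and 7 fell, and the share that fell, 3.21%, was lower than the 8.80% of all genes (odds ratio 0.341, Fisher's exact test, two-sided, p = 0.0016). This p was 0.0625 without basal 9A1 replicate 1, 0.192 without basal 9A1 replicate 2, 0.367 without basal 14B3 replicate 1 and 0.152 without day 1 14B3 replicate 2. With 1 array left out, the number risen at 1 day ran from 2 (without basal 14B3 replicate 1 or either day 1 14B3 array) to 24 (without day 1 9A1 replicate 1). The number fallen ran from 4 (without basal 14B3 replicate 2 or either day 1 14B3 array) to 18 (without basal 9A1 replicate 1 or day 1 9A1 replicate 1). The fatty acid transporter gene Cd36 rose by 4.47 ± 0.56, Cldn23 by 4.04 ± 0.60, Cd302 by 3.05 ± 0.58 and Efna1 by 2.86 ± 0.71. Cd109 fell by 3.70 ± 0.53, and lower too were Cldn6 (-2.89 ± 0.66), the ephrin receptor gene Epha4 (-2.83 ± 0.28) and the tetraspanin gene Cd9 (-2.83 ± 0.31). Cldn6 changed by -0.71 in 9A1 and -5.08 in 14B3, so its mean describes neither line, and the difference did not pass the interaction test (adjusted p = 0.936). Leaving out basal 9A1 replicate 1 and replicate 2 in turn gave 5.28 and 3.65 for Cd36, 4.87 and 3.20 for Cldn23, 3.89 and 2.21 for Cd302, 3.88 and 1.85 for Efna1, -4.44 and -2.96 for Cd109 and 6.02 and 3.14 for Epcam. Basal Cd36 lay under the floor of 5 on 3 of 4 arrays (4.09 to 4.73) and at 7.34 on 9A1 replicate 1, so background limits its rise. In the marker panel Epcam, an epithelial adhesion molecule on chromosome 17 from 87635979 to 87651127, rose by 4.58 ± 0.97 (23.9-fold, adjusted p = 0.00556), with 12.6 on basal 9A1 replicate 1 against 6.86 to 7.48 on the other basal arrays. Cd24a (chromosome 10, 43579169 to 43584265), a mucin-like progenitor marker, fell by 2.08 ± 0.38 (4.23-fold), and the hyaluronan receptor gene Cd44 (chromosome 2, 102811141 to 102901669) by 2.17 ± 0.49 (4.51-fold). Not passing the test were Afp at 1.27 ± 0.75, Krt19 at -0.13 ± 0.09, Sox9 at -0.83 ± 0.56, Dlk1 at -0.01 ± 0.29 and Prom1 at -0.01 ± 0.51. With basal 9A1 replicate 1 left out Afp rose by 2.15 (adjusted p = 0.0108), Sox9 fell by 1.42 (adjusted p = 0.0343) and Prom1 rose by 0.70 (adjusted p = 0.0332), while without replicate 2 Prom1 fell by 0.71 (adjusted p = 0.0404).

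At 5 days limma called 5591 genes, 2664 higher and 2927 lower, and 2786 of them differed at least 2-fold. Of the 5591, 5567 had the same sign in both lines, again favoured by calling genes on the mean of both. Without basal 9A1 replicate 1 the count was 6372, and 26 of the 55 called genes that the rule names then differed by over 1.5-fold more, all of them still called. Of the same 55, 26 differed by over 1.5-fold less without basal 9A1 replicate 2, and 0 lost their call. Without day 5 9A1 replicate 1 and replicate 2 in turn, Bex1 changed by -5.53 and -4.20 and Rrm2 by -5.44 and -4.02. Of the 55, 3 lost their call without some array: Ndrg1 without basal 14B3 replicate 1 (adjusted p = 0.0546), Marveld3 without that array, day 5 9A1 replicate 1 or day 5 14B3 replicate 1 (up to 0.0709), and Ocln without any of these 3 or day 5 14B3 replicate 2 (up to 0.0844). All 10 lists were called without any 1 array.

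Between 1 and 5 days of aggregate culture, the later part of the time course, 2 unnamed transcripts, 2010106E10Rik and 2210407C18Rik, rose by 8.39 ± 0.83 and 7.53 ± 1.32, the chloride channel accessory gene Clca4b by 8.17 ± 1.32, Cyp2c29 by 7.18 ± 0.46 and the sulfate transporter gene Slc13a1 by 7.15 ± 0.95. The 1 day mean of 2010106E10Rik, 3.84, and the 5 day mean of Aldh3a1, 4.71, lie under the floor of 5, so background limits the size of these 2 changes. Aldh3a1 fell by 4.66 ± 0.55, F2r fell by 4.34 ± 0.54, the collagenase gene Mmp13 by 4.19 ± 0.41, gelsolin (Gsn), which severs actin, by 3.85 ± 0.38 and Cnn3 by 3.55 ± 0.48. Of the panel, Cd24a fell by 2.02 ± 0.38 (adjusted p = 0.00602) and Cd44 fell by 1.79 ± 0.49 (adjusted p = 0.0294), whereas Alb, at 3.75 ± 1.23, and Epcam, at 2.77 ± 0.97, did not pass. Alb, Epcam, Afp (1.67) and Prom1 (0.80, with a 1 day mean of 4.69, under the floor) passed when either basal 9A1 array was left out. Basal arrays do not enter this comparison, and the changes in Alb and Epcam stayed at 3.75 and 2.77. These arrays act only through the estimate of the spread that all groups share, to which the unlike basal 9A1 arrays add. On the arrays compared, Epcam lay at 9.93 to 10.6 at 1 day and at 12.9 to 13.2 at 5 days. Alb also passed without day 1 9A1 replicate 1 (4.40, adjusted p = 0.0491) and Krt19 without day 5 9A1 replicate 2 (-0.29, adjusted p = 0.0465).

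Of the hepatocyte genes 19 of 38 rose between 1 and 5 days (camera adjusted p = 2.38e-09, adjusted p = 0.509 with an estimated correlation). Hypoxia and glycolysis genes rose in 11 of 25 cases (camera adjusted p = 2.04e-05, adjusted p = 0.553 with an estimated correlation), interferon response genes in 11 of 24 (camera adjusted p = 5.06e-05, adjusted p = 0.509 with an estimated correlation), and cholesterol synthesis genes in 8 of 19 (camera adjusted p = 7.1e-05, adjusted p = 0.561 with an estimated correlation). In the list of stress response and amino acid starvation 8 of 22 rose and 3 fell (camera adjusted p = 0.0124, adjusted p = 0.509 with an estimated correlation). Mitosis genes fell in 26 of 29 cases (camera adjusted p = 4.79e-14, adjusted p = 0.509 with an estimated correlation). DNA replication genes fell in 8 of 31 cases and 1 rose (camera adjusted p = 0.000469, adjusted p = 0.561 with an estimated correlation). Mesenchymal and contractile genes fell in 11 of 27 cases (camera adjusted p = 0.000548, adjusted p = 0.511 with an estimated correlation) and extracellular matrix genes in 9 of 26 (camera adjusted p = 0.000588, adjusted p = 0.243 with an estimated correlation). Adjusted over the list alone the counts in the same order were 24, 13 and 12 risen, 9 risen and 1 fallen, 9 risen and 4 fallen, 26 fallen, 12 fallen and 1 risen, 12 fallen and 1 risen, and 11 fallen. With 1 array left out the number that rose ran from 4 to 15 for hypoxia and glycolysis, 4 without any 1 of the 5 arrays with counts given below, and from 4 to 17 for cholesterol synthesis, 17 without day 1 9A1 replicate 2. The number that fell ran from 2 (without day 1 14B3 replicate 1 or day 5 14B3 replicate 2) to 14 (without either basal 9A1 array) for DNA replication, from 7 (without day 5 9A1 replicate 2 or day 5 14B3 replicate 1) to 13 for contractile genes, from 4 (without day 1 14B3 replicate 1, day 5 9A1 replicate 2 or day 5 14B3 replicate 2) to 11 for extracellular matrix and from 0 to 4 for the stress list. In all, limma called 3430 genes, 1848 higher and 1582 lower, and with quantile normalisation 1788 higher and 2141 lower. Without day 1 14B3 replicate 1 and replicate 2 the count was 1973 and 1935, without day 5 9A1 replicate 2 1899 and without day 5 14B3 replicate 1 and replicate 2 1821 and 1888, and Cd44 lost its call without each of 6 arrays, namely these 5 and day 1 9A1 replicate 1 (adjusted p up to 0.102, without day 5 9A1 replicate 2).

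Between the lines, averaged over the cultures, 9A1 had more of the peptidase genes Pm20d1 (2.97 ± 0.42, adjusted p = 0.031), Enpep (2.90 ± 0.39, adjusted p = 0.0286) and Mep1a (1.52 ± 0.14) and of the class I antigen genes H2-Q2 (1.61 ± 0.10, adjusted p = 0.00124) and H2-K1 (1.57 ± 0.22), whose probe sets can hybridise with relatives. For H2-Q2 the lines differed at 5 days, 8.32 against 3.61, while in basal culture (3.49 and 3.44) and at 1 day (3.55 and 3.47) both lay under the floor of 5, so the 1.61 is the mean of 1 difference against background and 2 near 0. It had less of Gatm, of creatine synthesis (-2.42 ± 0.31), the lipase inhibitor gene G0s2 (-2.07 ± 0.28), Morc4 (-1.84 ± 0.27), the prostaglandin synthase gene Ptgs2 (-1.66 ± 0.19), 3110039M20Rik (-1.63 ± 0.12) and Chac1 (-1.43 ± 0.18). In basal culture alone, Ptgs2 (-3.35 ± 0.33), Chac1 (-3.24 ± 0.32) and the proteoglycan gene Acan (-2.02 ± 0.19) were lower in 9A1 (adjusted p = 0.0148 each, 2 arrays per line, limma).

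Among the gene lists, camera called 10 between the lines. In 9 of them 0 members passed on their own, so the direction is that of the list as a whole. Mitosis (camera adjusted p = 6.27e-11), cholesterol synthesis (5.02e-08) and DNA replication (8.53e-07) were lower in 9A1 and hepatocyte function (3.39e-06) higher, each with adjusted p = 0.420 with an estimated correlation. Stress response and amino acid starvation was lower in 9A1 (camera adjusted p = 3.39e-06), with 1 of 22 members passing and 10 adjusted over the list alone, and TGF-beta and BMP targets (5.99e-05), biliary epithelium (0.000999) and extracellular matrix (0.0297) were higher, each with adjusted p = 0.272 with an estimated correlation. With that correlation and 1 array left out, the stress list was called only without basal 14B3 replicate 1. Cell cycle inhibitors (0.0188) and interferon response (0.0334) were higher, each with adjusted p = 0.557 with an estimated correlation. Adjusted over the list alone, 6 cholesterol genes were lower, as was 1 extracellular matrix gene, against the direction of its list, and 4 hepatocyte genes, 3 TGF-beta and BMP targets and 1 interferon gene were higher. Basal 9A1 replicate 1 and day 1 9A1 replicate 2 belong to 1 line, and without the first of them the hepatocyte list was not called (adjusted p = 0.0654). Extracellular matrix (up to 0.348, without basal 9A1 replicate 2), cell cycle inhibitors (up to 0.582, without day 1 9A1 replicate 1) and interferon response (up to 0.442, without basal 9A1 replicate 1) were each lost without some arrays.

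Limma called 43 genes between the lines, 22 higher and 21 lower in 9A1, or 37 and 23 with quantile normalisation, and 3 genes in basal culture. Leaving out any 1 of the 12 arrays moved the first count by over 1.5 times, from 2 without basal 14B3 replicate 2 to 807 without basal 9A1 replicate 2, with 163 without basal 9A1 replicate 1, 490 and 279 without day 1 9A1 replicate 1 and replicate 2, and 1673 without basal 9A1 replicate 1 and day 1 9A1 replicate 2 together, so the count depends on which arrays are kept. Leaving out any of 10 arrays so moved the count in basal culture, from 0 to 1495. Of the 11 genes named over the cultures, 3110039M20Rik passed without any 1 array and H2-Q2 in each of the 10 fits that tested it, as it lay under the floor without either day 5 9A1 array. Of the 3 in basal culture 0 passed without every array in turn, with an adjusted p of 0.173 for Ptgs2 and Chac1 without basal 14B3 replicate 2.

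Whether the lines responded differently was tested by an interaction. In the simulation this test recovered 2% of 2-fold differences at 1 day and 1% at 5 days, so genes not called may still differ. At 5 days 6 genes rose more in 9A1. H2-Q2, on chromosome 17 from 35342307 to 35346764, had a difference between 5 days and basal culture of 4.83 in 9A1 and 0.17 in 14B3, which differ by 4.66 ± 0.26 (adjusted p = 0.00029, 2 arrays per line and culture, limma). In the other 5 groups its mean lay between 3.44 and 3.61, under the floor of 5, so background limits how large this difference can come out. The differences were 3.15 ± 0.34 for Mfsd4b1, 3.07 ± 0.26 for the kinase gene Mylk3, 3.03 ± 0.28 for the monocarboxylate transporter gene Slc5a8 and 3.02 ± 0.34 for Mep1a, a brush border protease. Meltf, outside the naming rule and named after its value was seen, had 2.44 ± 0.30 (adjusted p = 0.0441). The other group means of Slc5a8, 4.11 to 4.82, were also under the floor and those of Mfsd4b1, 4.29 to 5.00, at or under it, so the same limit holds for these. Those of Mylk3, 4.95 to 5.50, and Meltf, 5.37 to 5.53, lay near the floor, so background may limit their differences too. Of the 5 rule-named genes H2-Q2 passed in each of the 10 fits with 1 array left out that tested it, and without either day 5 9A1 array it and Slc5a8 were not tested. The other 4 each missed the test without at least 1 array. In all, 11 of the arrays moved the count of 6 by over 1.5 times, from 1 without basal 14B3 replicate 2 to 706 without basal 9A1 replicate 2. At 1 day limma called 0 genes, with 522 at an unadjusted p under 0.05, and also 0 with robust moderation, array weights or quantile normalisation, 4 without basal 9A1 replicate 1 and day 1 9A1 replicate 2 together, and leaving out any of 3 arrays gave a count above 0, up to 1009 without day 1 9A1 replicate 1.

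Across the 15781 genes, the changes in 9A1 and 14B3 correlated with r = 0.653 at 1 day and 0.866 at 5 days (Spearman 0.531 and 0.817). Genes are not independent replicates, so no p is given. The slope of the 9A1 on the 14B3 change was 0.513 at 1 day and 0.717 at 5 days, and 0.840 and 1.02 without basal 9A1 replicate 1. Without basal 9A1 replicate 2, r was 0.186 at 1 day and 0.597 at 5 days.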

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

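The tests of a swap, of a mixture and of RNA degradation on the hepatocyte level for basal 9A1 replicate 1, and the intestinal gene lists, were chosen after the results they bear on were seen. In 78 sets of 4 arrays (26 measures in 3 cultures, both lines together) 12 had 1 array far from the other 3, where chance gives about 5% of sets. In each set, the array named lay apart from the other 3 of its culture. The measures share arrays and some genes, so 1 unlike array can flag several sets and the 12 are not separate events. All 12 fell on 9A1 arrays: 4 on basal replicate 1, 3 on day 1 replicate 1, 4 on day 5 replicate 1 and 1 on day 5 replicate 2.

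Basal 9A1 replicate 1 stood apart on 4 measures. Its first principal component score was -11.7 (others 69.5 to 78.8), its mean hepatocyte level 8.22 (others 6.12 to 6.23), its mean mitosis level 9.79 (others 10.8 to 10.9) and its mean Notch pathway level 7.78 (others 8.17 to 8.19). A swap of labels with a 5 day array is argued against, because no 5 day array lies among the basal ones: the highest score of these is -61.4. A mixture of basal and 5 day RNA in 1 share cannot be told apart from other causes: rising genes gave a median share of 0.414 and falling genes 0.618, a difference of 0.204 with wide overlap (quartiles 0.228 to 0.653 and 0.467 to 0.775). RNA degradation as the cause of the high hepatocyte level is argued against only in part. Loss of RNA removes transcripts, whereas the 8.22 lies above the other basal arrays by more than their range. RMA brings all arrays to a common distribution, so levels are relative and loss of some transcripts can raise others, for which no bound was set. For the lower mitosis and Notch levels RNA degradation cannot be told apart from other causes, since the 3' minus 5' differences of beta-actin, 0.262, and of the transferrin receptor, 1.07, lie within those of the other arrays (0.182 to 0.361 and 0.870 to 1.88) and that of 18S RNA, -0.0710, is the lowest of the arrays, while that of Gapdh, 0.0183, is above the highest other of 0.0168. Cells of this line that had begun to differentiate in basal culture may also account for it, which was not tested.

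The 2 day 1 9A1 arrays differed over many genes, with an SD of the pair difference of 0.779 against 0.300 in 14B3, which does not say which of them departs: replicate 2 has the narrowest spread of values, an SD of 2.13, while replicate 1 lay apart on 3 list means given below, and limma called 4793 genes at 1 day without replicate 1 and 2715 without replicate 2. A narrower distribution left by the normalisation is argued against, since after quantile normalisation the SD was still 2.79 times that of 14B3 (2.59 before). RNA degradation of replicate 2 cannot be told apart from other causes, since its differences for beta-actin, 0.361 (next 0.340), the transferrin receptor, 1.88 (next 1.65), and 18S RNA, 2.10 (next 1.18), are the highest of the arrays but its Gapdh difference of 0.0160 lies within the range of the others, -0.126 to 0.0183. No biological explanation was tested.

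Intestinal genes were among those that rose most at 5 days, and lists for gut and other organs were written after the largest changes were seen, leaving out the genes seen among them. Of 31 tested absorptive gut genes 23 rose and 0 fell, with a median of 3.06 (quartiles 0.571 to 4.11; camera adjusted p = 7.64e-10, adjusted p = 0.754 with an estimated correlation), and Lct, Npc1l1 and Myo1a rose by 4.83 ± 0.27, 4.98 ± 0.34 and 5.40 ± 0.95. Intestinal tissue in the samples is argued against by the secretory genes, which such tissue would raise together, with a median of 0.0563 over 14 genes (quartiles -0.0369 to 0.209), where Spink4 rose by 3.98 ± 0.72, Fcgbp fell by 1.19 ± 0.17 and the goblet cell gene Muc2 changed by -0.04 ± 0.15, and cross-hybridising probe sets by a median of 2.87 over the 28 absorptive genes with an unsuffixed probe set. No 1 array decides it, since the lowest median with an array left out was 2.17 (without basal 9A1 replicate 2). A candidate explanation is that an absorptive epithelial programme, which includes genes such as Abcg8 and Dpp4 that liver also expresses, rises in aggregates. The 8 genes that did not pass were Cdx1, Espn, Reg3g, Slc26a3, Slc2a5, Slc5a1, Slc6a19 and Usp2. Their 5 day means lay between 4.78 (Slc26a3) and 6.74 (Slc2a5), so the rise did not cover the whole list. Basal levels on this list were mixed, so some of its genes were already high before aggregation. Basal means were 10.1 for Cdx2, 11.9 for Cdh17 and 12.3 for Krt20, which rose by 0.84 ± 0.16, 1.22 ± 0.19 and 1.37 ± 0.31. Those of Lct, Mgam and Treh were 5.37, 4.55 and 5.47.

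The other sets were as follows. On day 1 9A1 replicate 1 the mean level was 8.60 for extracellular matrix (others 8.23 to 8.28), 10.04 for hypoxia and glycolysis (others 10.41 to 10.46) and 9.41 for cholesterol synthesis (others 10.8 or more). On day 5 9A1 replicate 1 it was 8.60 for fetal liver and imprinted growth (others 7.79 to 7.84), 8.98 for progenitor surface markers (others 8.53 to 8.56), 7.86 for extracellular matrix (others 7.55 to 7.57) and 7.93 for the Notch pathway (others 7.60 to 7.62). On day 5 9A1 replicate 2 it was 6.41 for Wnt targets (others 6.67). The change at 5 days differed between the lines by the interaction test for 6 genes, being larger in 9A1 by 4.66 for H2-Q2, 3.15 for Mfsd4b1, 3.07 for Mylk3, 3.03 for Slc5a8, 3.02 for Mep1a and 2.44 for Meltf. H2-Q2 lay at 3.44 to 3.61 in the other 5 groups, under the floor of 5, Slc5a8 at 4.11 to 4.82 and Mfsd4b1 at 4.29 to 5.00, so background limits the size of these differences. Mylk3, at 4.95 to 5.50, and Meltf, at 5.37 to 5.53, lay near the floor there, so background may limit theirs too.

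Whether chance can be excluded was asked by regrouping the same arrays, in a fit with the arrays compared and line or culture as a term. For genes at 1 day, 1 of 35 splits, the real one, gave as many (1264, highest other 64). For genes at 5 days it was 1 of 35 (6631, highest other 0) and between 1 and 5 days 1 of 35 (3926, highest other 0). For genes between the lines it was 1 of 100 (5, highest other 1), a count that depends on which arrays are kept. In each the real split alone gave as many, which is the lowest share that the splits allow. For the comparisons of cultures this rank argues against chance. Between the lines, 5 genes against 1 are too few for a conclusion. The other splits mix the groups, which puts a real difference into their spread and keeps their calls low. Their counts are thus no measure of how many calls chance would give. For surface families at 5 days, 1 of 35 (70, highest other 0) adds nothing, since the other splits called 0 genes in all. For the number of lists called chance cannot be excluded: 20 of 35 splits gave as many at 1 day (7, highest other 14), 9 of 35 at 5 days (11, highest other 14) and 12 of 100 between the lines (11, highest other 13).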

How the results depend on the processing

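Leaving out basal 9A1 replicate 1 and day 1 9A1 replicate 2 together was chosen after the data were seen, although the data do not say which of the 2 day 1 9A1 arrays departs. The counts of genes at 1 day, 5 days and between them became 5302, 8117 and 6704, those between the lines 1673 and in basal culture 375, those of the interactions 4 and 147, the lists at 1 day 11, and the correlation of the lines at 1 day 0.845. With it, Prom1 at 5 days changed from -0.01 to 0.70 (also 0.70 without basal 9A1 replicate 1 alone, and -0.71 without basal 9A1 replicate 2), and between the lines the direction turned for hypoxia and glycolysis (adjusted p = 0.00114, 0.00541 without basal 9A1 replicate 1 alone, and 0.977 without basal 14B3 replicate 1), YAP targets (0.0103) and interferon response (0.828). Hypoxia and glycolysis was then lower in 9A1, as it was without basal 9A1 replicate 1 alone. Without basal 9A1 replicate 2 alone this list was called in the opposite direction, higher in 9A1. Its direction thus depends on which basal 9A1 array is kept. The cause of these turns was not tested.

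With 1 array left out, where the lone array of a group is assumed to vary like the others, counts ranged from 853 to 4793 at 1 day, 4166 to 6895 at 5 days and 1821 to 4958 between them, 2 to 807 between the lines and 0 to 1495 in basal culture, 0 to 1009 and 1 to 706 for the interactions at 1 and 5 days, 5 to 13, 10 to 12 and 8 to 13 lists at 1 day, 5 days and between lines, and 50 to 74 surface genes. The correlation of the lines ranged from 0.186 to 0.815 at 1 day and 0.597 to 0.927 at 5 days.

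Other settings moved these counts by over 1.5 times. Except for the stricter thresholds, the cause was not tested, and 14B3 alone gave more calls although it has fewer arrays. Every probe set on its own gave 3745, 9495 and 5755 at 1 day, 5 days and between them and 6 in basal culture. Array weights gave 1283 at 1 day, 0 in basal culture and 14 for the interaction at 5 days. Only the cultures compared gave 955, 0 and 2 for the same. 9A1 alone gave 0, 279 and 31 at 1 day, 5 days and between them (limma, 2 arrays per culture), and 14B3 alone 5682 at 1 day and 5606 between them. A 2-fold minimum gave 965, 2786 and 1550, and 27 between lines; adjusted p under 0.01 gave 848, 3680 and 1592, 4 between lines, 0 in basal culture and 3 for the interaction at 5 days. The mean of probe sets gave 5 in basal culture and the additive model 5 between lines. With an estimated correlation 0 lists were called at 1 day, 0 at 5 days and 0 between lines. Fry called 5 lists at 1 day, 13 at 5 days, 9 between them and 1 between lines. Of these, 4, 9, 7 and 1 were also called by camera. Among the camera lists, fry did not call liver transcription factors, YAP targets and cholesterol synthesis at 1 day. At 5 days it did not call hypoxia and glycolysis (fry adjusted p = 0.0669).

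A replicate block gave 28 genes between the lines; the correlation of replicate residuals over the 15 pairs of groups ran from -0.30 to 0.50, above 0.1 in 5, so the numbers were not taken as pairs. The number of arrays limits these results, and RMA values do not give signal over background. Over the settings tried, 0 named genes that had passed the test reversed. At 1 day 118 of 971 values for named genes fell short of the threshold and 9 passed that had not, at 5 days 54 and 8 of 1619, and between these 18 and 27 of 539. These totals include genes not called in the main fit. Of the named genes called there, 0 of 27 at 1 day kept their call under every setting, which include each line alone. At 5 days 10 of 55 did, and between these 1 of 12. Values fell short in 82 of 262 cases between the lines, 27 of 72 in basal culture and 27 of 116 for the interaction at 5 days.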

Other observations

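The lists for other organs were chosen after the results were seen, and so were the genes named as examples here. At 5 days Myc fell by 2.24 ± 0.27, after a fall of 2.63 ± 0.27 at 1 day, and Hmga2, a chromatin protein of fetal and tumour cells, by 4.31 ± 0.49. Cyclin D1 (Ccnd1) fell by 3.19 ± 0.63 and Apcdd1 by 3.30 ± 0.34, 4 of the 16 Wnt targets in all (camera adjusted p = 0.118). Of 18 Notch pathway genes 8 fell, such as Nrarp by 1.76 ± 0.39 and Notch1 by 1.37 ± 0.35, and 3 rose, such as the ligand gene Dll1 by 1.63 ± 0.37 (camera adjusted p = 0.0974). Of 22 stress genes 9 fell and 4 rose, with Psat1 lower by 4.66 ± 0.39 and Phgdh by 2.80 ± 0.35 and Ddit3 higher by 1.85 ± 0.41 (camera adjusted p = 0.0974). Both of these lists were called downward with some 1 array left out, Notch without basal 9A1 replicate 1 (adjusted p = 0.0372) or day 5 9A1 replicate 1 (0.0463) and stress without basal 9A1 replicate 1 (0.0486), basal 9A1 replicate 2 (0.0358) or basal 14B3 replicate 1 (0.0234), and neither with an estimated correlation (lowest adjusted p of any list with 1 array left out 0.198). The number of Notch genes that fell ran from 2 (without basal 14B3 replicate 1) to 11 (without basal 9A1 replicate 1).

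Of 22 progenitor surface markers 3 rose and 6 fell (camera adjusted p = 0.323), with the peptidase gene Anpep higher by 4.52 ± 0.56 and Ly6e lower by 4.07 ± 0.78, to a mean of 4.96, under the floor of 5. Of 23 biliary genes 6 rose and 3 fell (adjusted p = 0.291), including the chloride channel gene Cftr higher by 3.26 ± 0.64 and Krt7 lower by 1.72 ± 0.43. Of 24 integrins and matrix receptors 2 rose and 5 fell (0.554), of 22 cell cycle inhibitors 4 rose and 2 fell (0.533), of 19 cholesterol genes 2 rose (0.118, and 10 with 0.0172 and 0.0175 without day 1 9A1 replicate 1 and replicate 2), of 15 TGF-beta and BMP targets 3 rose and 3 fell (0.696), of 15 fetal liver genes 3 fell (0.696) and of 21 inflammation genes 2 rose and 4 fell (0.696). For the TGF-beta and BMP targets the median was -0.21 and the mean 0.09, so these differ in sign. With 1 array left out, 8 cell cycle inhibitors rose and 7 inflammation genes fell without basal 9A1 replicate 1, the TGF-beta and BMP targets that fell ran from 1 (without basal 9A1 replicate 2, among others) to 5 (without either day 1 9A1 array), and 1 biliary gene fell without basal 9A1 replicate 2, basal 14B3 replicate 2 or either day 5 14B3 array.

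Of the lists written for other organs, kidney had a median change of 0.01 over 11 genes at 5 days, stomach 0.10 over 11, pancreas 0.03 over 10 and smooth muscle -0.01 over 8, of which 4 are also in the fixed lists.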
